A study of Rattus norvegicus with 14 samples.

How the data were processed

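Gene expression was measured in cultured rat fibroblast-like synoviocytes (FLS), the fibroblasts of the joint lining, on 7 Agilent rat arrays with 2 colours each. Per the labels' protocols, cells near confluence were kept for 24 h in medium with 1% fetal calf serum and then for 24 h in medium with 1% serum with or without the added agents. The agents were tumour necrosis factor alpha (TNF), an inflammatory cytokine, and SB203580, an inhibitor of the p38 mitogen-activated protein kinase. Samples come as numbered pairs, Exp 1 to Exp 4 with and without TNF and Exp 6 to Exp 8 with and without "SB80". The labels do not expand "SB80", and SB203580 is the only agent of that kind their protocols name. A TNF concentration, 10 ng per ml, stands only in the labels of Exp 1. Whether the samples labelled −SB80 received TNF is not stated outright, and the protocol text of the Exp 6 sample labelled +SB80 names TNF alone. No Exp 5 was analysed here. Nothing in the labels says that the Exp numbers are separate cultures or animals, so p-values measure only the spread between these arrays, which may be technical.

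The deposited scanner files hold spot intensities (mean signal and local background of each dye) together with the scanner software's processed signals and its log10 ratio of red over green. They were made with Agilent Feature Extraction A.7.5.1, per the file headers. The 2 files of each Exp number were identical byte for byte, for all 7 pairs, so an Exp number is 1 array and its 2 samples are the 2 channels. The authors' value table lists, for each sample, a linear intensity that equalled the processed signal of a single channel in 100% of entries at a relative tolerance of 1e-04. By that match the +TNFa samples were assigned to Cy3 on all 4 TNF arrays, and the +SB80 samples to Cy5 on all 3 SB80 arrays. This assignment holds no dye swap within either comparison, but it does not show how the extracts were dyed. Medians of the value table per sample ran from 418.7 to 788.5 on the linear scale. The deposited log10 ratio equalled that of the processed red over green signal, to within 1e-04, in 100% of spots for which the software used no surrogate value.

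Each array had 43628 features, 2256 of them controls, and 41012 gene probes. The median mean signal of the gene probes was between 122 and 445 per channel over median backgrounds of 29 to 47, and between 85.7% and 97% of probes were well above background by the scanner software's own flag. Between 14 and 359 probes per channel were saturated. Outlier flags removed 0.23% of gene-probe values. The number of arrays, 4 and 3, limits the precision.

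In R 4.3.3 with limma 3.58.1, signals were corrected with normexp at an offset of 50, normalized by loess within each array with control spots and outlier flags at weight 0, and averaged over the spots of a probe. Log2 ratios were turned to plus over minus by the dyes above. For a gene with several probes the probe with the highest mean log2 intensity was used. This left 36139 entries, of which 14793 carried a gene symbol. Probes were named through their RefSeq accession (10221), a gene number (2035), a symbol (4929), a synonym (1155) or a symbol in the description (174), with the names of assembly GRCr8, and 22498 probes kept the name in the files. Only names were taken from that assembly. Coordinates are those in the scanner files, whose genome build is not given in the sources used here, and whether a probe lies in an exon or a UTR was not analysed here.

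Both comparisons were fitted in a single limma model on the 7 arrays, with 1 coefficient each, moderated by eBayes, two-sided, with Benjamini-Hochberg adjustment over all entries and a threshold of 0.05. Each SE given with a limma fit is moderated, from a spread shared by the arrays of that fit, and n counts arrays. The ratio within an array carries the pairing: deviations of the channels of an array from their group means correlated across probes at 0.14 to 0.58 on the TNF arrays and 0.74 to 0.90 on the SB80 arrays. Gene lists, 24 in number and fixed before the data were examined together with the design and the rule for named genes, were tested with camera at a preset correlation of 0.01, adjusted over lists and comparisons, with fry and an estimated correlation beside it. Members listed only under a symbol other than the one used here were left out of the list tests. So 36 of 38 measured members were tested for the Wnt, BMP and bone remodelling list and 21 of 23 for the actin list. The complement, interferon and oxidative stress lists were tested on 22 of 23, 31 of 32 and 27 of 28. Counts of measured list members below are of those tested. Named genes were, per comparison, the 8 with the largest rise and the 8 with the largest fall among genes past the threshold that moved the same way on every array, or, where none passed, the 8 per direction with the smallest p. Up to 3 members of each list past the threshold were added, as were 19 measured core inflammatory genes whatever their result. The rule kept to genes with a symbol that were well above background. A gene that the rule names for the SB80 arrays alone is not reported here.

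Log ratios of the TNF arrays opposed each other, which the design had not foreseen. Exp 1 and Exp 2 correlated across all probes at −0.55, Exp 1 and Exp 3 at −0.21, Exp 2 and Exp 4 at −0.32 and Exp 3 and Exp 4 at −0.29, against 0.53 for Exp 1 with Exp 4 and 0.33 for Exp 2 with Exp 3. With pairs below −0.3 on arrays assigned the same dye orientation, the direction of the TNF ratio is not settled. The comparison is therefore given as labelled, which is the planned result, and with the sign of Exp 2 and Exp 3 turned. The turned fit, and every value from it, was chosen after the data were seen, and its p-values are conditional on that choice. Turning Exp 1 and Exp 4 in their place gives the same sizes and p-values with every sign reversed.

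A probe saturated on every array of a group has only a bound, given as "at least", from channel values after loess and Aquantile. As labelled each group has 1 dye, so such a bound is open to dye bias, while each turned group holds 2 channels of either dye. Where the other group was saturated on some array too, no fold is given. The steps were tested on simulated data with the real spread of 35552 genes, 200 of them changed in each of 5 draws. Changed genes were drawn at random, each with 1 sign on every array of the comparison and with independent noise. At a log2 change of 1, the share recovered was 93.4% for the TNF comparison as labelled, 90.7% for the SB80 comparison, and 98.8% for the turned TNF comparison. At a log2 change of 0.5 these shares were 41.5%, 20.6% and 56.4%. The shares do not hold for genes whose ratios changed sign between the TNF arrays as labelled. Their spread was larger, as for Ptgs2 with an SE of 1.02 in the TNF comparison. Of the calls in these simulations 5.22%, 4% and 6.59% were false. A moved list of 30 genes was called in 5 of 5 draws in each, at an unadjusted camera p under 0.05. An unmoved list was called in 1 of 5 draws for the turned TNF comparison and in 0 for the other comparisons.

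Settings chosen before the data were examined were another normexp offset, plain subtraction, the scanner software's processed signals and log ratio, the value table, median centring, scale normalization between arrays, a filter on dim probes, the mean over probes, the arrays of a comparison alone, the channels as separate samples, array weights, a trended robust prior, a one-sample t per gene, other thresholds, an estimated correlation for lists, and leaving out each array. Added after the data were seen were the turned directions, a dye term in the turned fit, a correction of position gradients on the arrays (the median of each block of 6 by 12 spots subtracted), omission of saturated spots, and the average of Exp 1 with Exp 2 and of Exp 3 with Exp 4 as 1 replicate each. Exp 1 and Exp 2 were extracted by the scanner software on the same day and every other array on a day of its own, with 7 slides for 7 arrays.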

Results

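Transcript levels were measured in 14 samples of rat fibroblast-like synoviocytes, read as the 2 channels of 7 arrays. There were 4 samples labelled +TNFa and 4 labelled −TNFa (Exp 1 to Exp 4), and 3 labelled +SB80 and 3 labelled −SB80 (Exp 6 to Exp 8). The dimmest channels were the −TNFa channels of Exp 3 and Exp 4, with median mean signals of 124 and 122, and the brightest was the −TNFa channel of Exp 1 at 445. The first comparison asks which transcripts differ with TNF after 24 h. The second asks which differ with the p38 inhibitor, and the third sets the 2 responses side by side.

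With the labels taken as deposited, several TNF-responsive genes were far apart between the channels of an array, but in opposite directions on different arrays. Cxcl2, a neutrophil-attracting chemokine, had log2 ratios of 5.48 on Exp 1, −5.28 on Exp 2, −6.52 on Exp 3 and 5.64 on Exp 4. Ptgs2, the inducible cyclooxygenase, had 3.27, −3.36, −2.45 and 2.33, and Mmp9, a gelatinase, had 2.44, −2.83, −2.42 and 2.18 on the same arrays. Interleukin 6 (Il6) followed the same signs with 2.53, −2.61, −0.25 and 0.36, small on the latter 2 arrays. Other core genes did not follow them, such as Vcam1 with −0.13, 0.27, −1.22 and 1.77, or were near 0 on some arrays, such as Ccl5, Sod2 and Cxcl1. The 16 measured genes of NF-kappaB feedback and survival had medians of 0.66, −0.76, −0.61 and 0.80, with 15, 1, 3 and 14 members above 0.

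**Figure D1:**
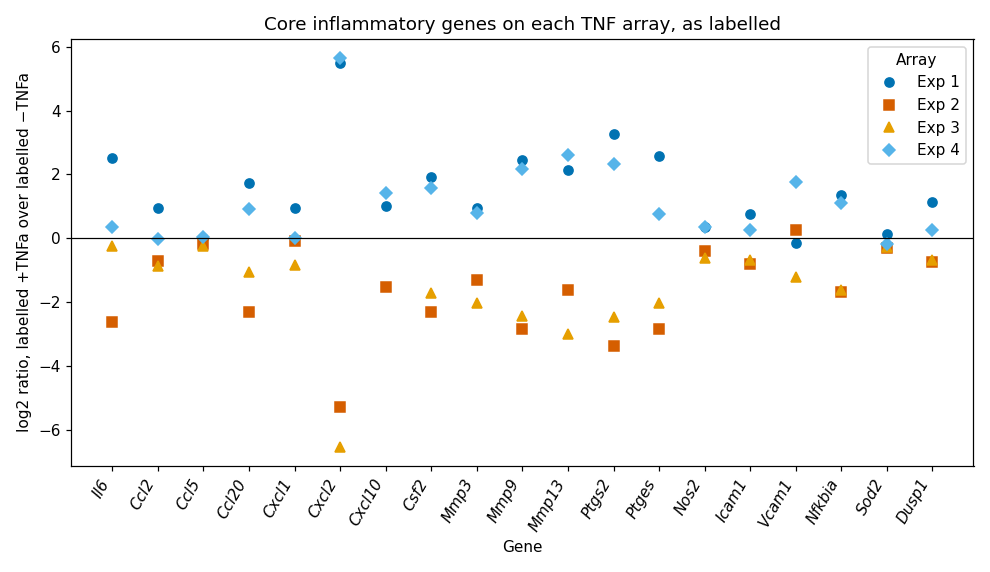
Log2 ratio of the sample labelled +TNFa over the sample labelled −TNFa (vertical axis) for 19 core inflammatory genes (horizontal axis), with a point per array. For Cxcl2 the points of Exp 1 and Exp 4 lie at 5.48 and 5.64 and those of Exp 2 and Exp 3 at −5.28 and −6.52.

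As labelled, 0 of 36139 genes passed the threshold by limma, the smallest adjusted p being 0.458, while 2605 had an unadjusted p under 0.05 against 1807 expected by chance. The one-sample t per gene called 0, the channels as separate samples called 0, and the scanner software's processed signals, its log ratio and the authors' value table called 47, 45 and 43. Of the 19 core genes, 0 passed, over all genes or adjusted over the list alone. The mean of Cxcl2 was −0.17 ± 2.03 (SE, n = 4) and that of Ptgs2 −0.05 ± 1.02 (SE, n = 4). Genes with the smallest p had small ratios of 1 sign on all 4 arrays, such as Rpl14, a ribosomal protein gene, at 0.59 ± 0.08, and Creb3l3 at 0.48 ± 0.07, both with an adjusted p of 0.458 by limma. With processed signals, the log ratio or the value table, Creb3l3, Apoc4 and Dgkh passed. Others were Apoc4 at 0.47, Kmt5al3 at 0.44, Dgkh at 0.39, Csdc2 at 0.55 and Sstr1 at 0.32, and on the other side Fgf11 at −0.30, Gpt2 at −0.27, Wnt8b at −0.30, Or51af1 at −0.25, Serpina5 at −0.39, Crh at −0.22, Atp2b3 at −0.25 and Ywhab at −0.26. For Gabra2 the −TNFa channel was not well above background on any array, giving a value at least 1.43-fold higher in the +TNFa samples, uncalled. Rpl14 was saturated on some arrays and its other probe had the opposite sign. All +TNFa samples were assigned to Cy3 and all −TNFa samples to Cy5. For genes with 1 sign on all 4 arrays, a dye bias of single genes therefore cannot be told apart from TNF as labelled.

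None of the 24 gene lists was shifted as labelled by camera, with adjusted p between 0.662 and 0.927, and with an estimated correlation the count was also 0. Adjusted over the list alone, 1 gene passed, the T-cell surface gene Cd5 at 0.33 (adjusted p 0.597 over all genes by limma), named after its value was seen. Median, mean and test differed in sign for chemokines, complement and acute phase, cytokines, macrophage and myeloid markers, immediate early genes, p38 and MAPK members, prostaglandin synthesis, synovial fibroblast markers and the Wnt, BMP and bone list, with medians from −0.02 to 0.03. Without Exp 1, 2, 3 or 4 the number of shifted lists was 2, 1, 1 and 4.

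**Figure D2:**
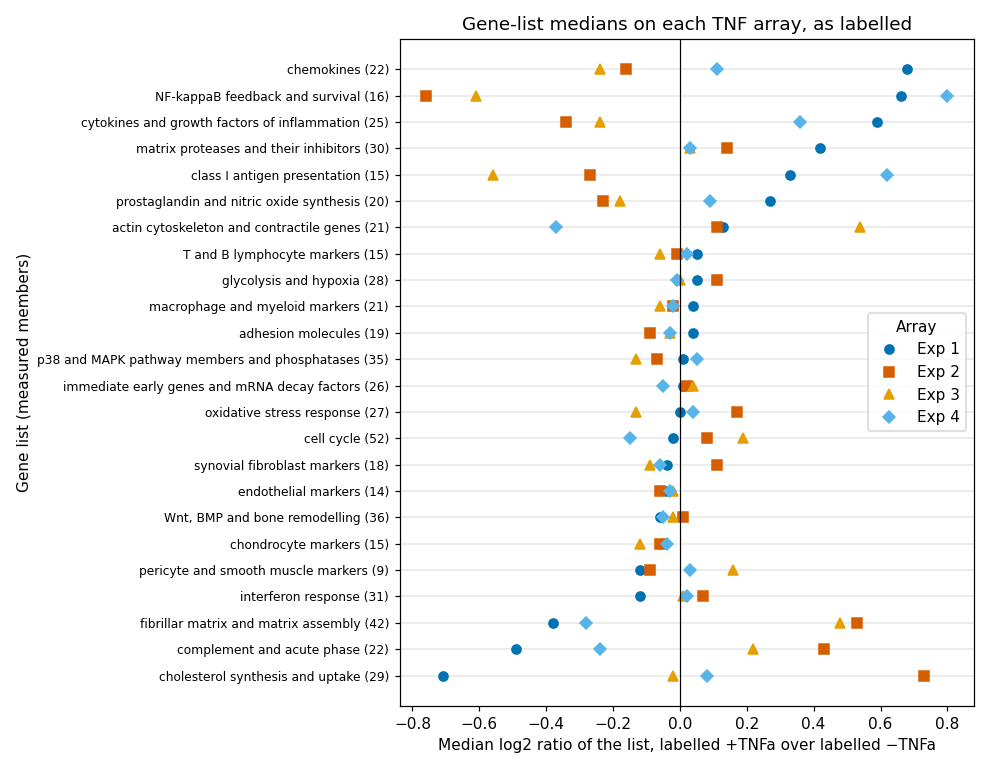
Median log2 ratio, labelled +TNFa over labelled −TNFa (horizontal axis), of each gene list (vertical axis, measured members in parentheses), with a point per array. For NF-kappaB feedback and survival the points lie at 0.66 and 0.80 on Exp 1 and Exp 4 and at −0.76 and −0.61 on Exp 2 and Exp 3.

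With the sign of Exp 2 and Exp 3 turned, several inflammatory genes were among the largest rises, along with genes of none of the lists. In what follows "rose" means higher in the sample labelled +TNFa on Exp 1 and Exp 4 and in the sample labelled −TNFa on Exp 2 and Exp 3, and the direction itself is not settled. Cxcl2 rose by a log2 fold of 5.73 ± 0.17 (SE, n = 4, limma adjusted p = 3.39e-07), with its bright channel saturated on 2 arrays. The SE values here are moderated and draw on the SB80 arrays too. The SD over the 4 TNF arrays was 0.55 for Cxcl2 and 1.46 for Fabp4. If Exp 1 with Exp 2 and Exp 3 with Exp 4 repeat the same extracts, n is 2. With these pairs averaged, 23 of the 51 named genes called in the turned fit still passed. The stromelysin Mmp10 rose by 3.88 ± 0.11, the cytokine interleukin 1 beta (Il1b) by 3.20 ± 0.24, Ptgs2 by 2.85 ± 0.17 and Mmp9 by 2.47 ± 0.11. Other large rises were those of Pcp4 (2.57 ± 0.12), the oxysterol hydroxylase Cyp7b1 (2.53 ± 0.17) and the AMP deaminase Ampd3 (2.50 ± 0.19). The largest falls were those of the Ras-related Rasd1 (−2.82 ± 0.23), the cell cycle regulator Rgcc (−2.55 ± 0.10), the fatty acid binding protein Fabp4 (−2.35 ± 0.42), type III collagen Col3a1 (−2.29 ± 0.13), G0s2 (−2.19 ± 0.28), apelin (Apln, −1.91 ± 0.19), Gadd45g (−1.84 ± 0.22) and Ccn5 (−1.83 ± 0.11). The rule for named genes admits only genes of 1 sign on every array, here after turning. In the coordinates of the scanner files, the Cxcl2 probe lies on chromosome 14 at 18677236 to 18677295, the Ptgs2 probe on chromosome 13 at 64448537 to 64448596 and the Col3a1 probe on chromosome 9 at 44318879 to 44318938.

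The turned limma fit called 1548 of 36139 genes, 719 that rose and 829 that fell, and 149 and 140 of these changed by a log2 fold of at least 1. Fitted on the TNF arrays alone it called 933, with Exp 1 and Exp 2 and also Exp 3 and Exp 4 averaged to 1 replicate each it called 385 (380 of them among the 1548), without Exp 1 it called 747 and without Exp 2 it called 799. The one-sample t called 0. Of the 19 core genes, 13 passed over all genes and 15 adjusted over the list alone. Il6 missed the threshold at 1.43 ± 0.37 (limma adjusted p = 0.0705), with turned ratios of 2.53 and 2.61 on Exp 1 and Exp 2 against 0.25 and 0.36 on Exp 3 and Exp 4. The adhesion molecule Vcam1 had 0.65 ± 0.29 (adjusted p = 0.368), from −0.13, −0.27, 1.22 and 1.77. Ccl5 (0.12), Cxcl1 (0.47, with saturated spots in both groups) and Sod2 (0.13) did not pass either, nor did the monocyte chemokine Ccl2 (adjusted p = 0.121), which was saturated in the brighter group on all 4 arrays and in the other on 2, so that no fold is given.

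Genes of NF-kappaB feedback and survival rose together in the turned fit. Of 16 measured, 9 rose, 1 fell and 6 did not pass (camera adjusted p = 8.9e-21, and adjusted p = 0.00661 with an estimated correlation). Adjusted over the list alone, 13 rose and 1 fell. The apoptosis inhibitor Birc3 rose by 2.40 ± 0.09, and the NF-kappaB inhibitors Nfkbie and Nfkbia by 1.66 ± 0.09 and 1.44 ± 0.11 (SE, n = 4). Of 25 cytokines and growth factors 10 rose and 1 fell (adjusted p = 3.63e-12, and adjusted p = 0.0382 with an estimated correlation), or 15 and 2 adjusted over the list alone. Among these, the granulocyte factor Csf3 and the morphogen Bmp2 each rose by 2.05, and Csf2 by 1.88 ± 0.13. Of 22 chemokines 7 rose and 1 fell (adjusted p = 9.77e-07, and adjusted p = 0.0346 with an estimated correlation), or 10 and 2 adjusted over the list alone. Cxcl10 rose by 1.31 ± 0.15 on the 3 arrays with a value, and the bright group of Cxcl3 and Ccl20 was saturated on all 4 arrays, giving rises of at least 3.52-fold and 2.83-fold on the normalized scale.

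Genes of the prostaglandin and nitric oxide synthesis list, which includes prostaglandin receptors, also rose, 6 of 20 with 1 fall. For this list camera gave an adjusted p = 4.74e-05, and adjusted p = 0.0382 with an estimated correlation. Adjusted over the list alone, 7 rose and 1 fell. Prostaglandin E synthase (Ptges) rose by 2.06 ± 0.27, Gch1, which makes the cofactor of nitric oxide synthase, by 2.01 ± 0.13, and the inducible synthase Nos2 by 0.43 ± 0.10. Of 15 genes of class I antigen presentation 6 rose and 0 fell (adjusted p = 4.23e-10, lost at adjusted p = 0.0618 with an estimated correlation), or 9 and 0 adjusted over the list alone, with RT1-CE5 at 0.64, Tapbp at 0.57 and RT1-Aw2 at 0.54. RT1 genes are near-identical copies, and their probes may not tell them apart. Among 30 matrix proteases and their inhibitors 8 rose and 3 fell (adjusted p = 0.0273, lost at adjusted p = 0.141 with an estimated correlation), or 10 and 8 adjusted over the list alone. That list had a median of −0.00 against a mean of 0.39. The collagenase Mmp13 rose by 2.34 ± 0.18 with 2 arrays saturated in its bright channel. Stromelysin Mmp3 passed too, but it was saturated in the bright group on all 4 arrays and in the other on 1, so that no fold is given.

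Matrix genes fell. Of 42 genes of fibrillar matrix and matrix assembly 18 fell and 0 rose (camera adjusted p = 6.29e-13, and adjusted p = 0.0179 with an estimated correlation), or 23 and 1 adjusted over the list alone. Besides Col3a1, osteoglycin (Ogn) fell by 1.67 on the log2 scale and thrombospondin 2 (Thbs2) by 1.51. Of 22 genes of complement and acute phase 7 fell and 2 rose (adjusted p = 0.000372, lost at adjusted p = 0.194 with an estimated correlation), or 9 and 2 adjusted over the list alone. The complement protease genes C1s, saturated on 2 arrays, and Cfd were each at −1.03, while the acute phase gene Saa3 rose by 1.94 ± 0.23. Of 52 cell cycle genes 6 fell and 1 rose (adjusted p = 0.000524, lost at adjusted p = 0.377 with an estimated correlation), or 10 and 1 adjusted over the list alone. The kinases Bub1 and Cdk1 were both at −0.79, and Gmnn, an inhibitor of replication licensing, rose by 0.85 ± 0.17.

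The cell cycle list had a median of −0.03 on Exp 1 with Exp 2 and −0.14 on Exp 3 with Exp 4, and the last 2 shifted lists also differed between these pairs. Of 29 genes of cholesterol synthesis and uptake 1 fell, the synthase Hmgcs1 at −1.18 ± 0.25 (camera adjusted p = 8.7e-07, lost at adjusted p = 0.377 with an estimated correlation), or 11 adjusted over the list alone. The list's median was −0.73 on Exp 1 with Exp 2 and −0.04 on Exp 3 with Exp 4. Of 21 actin cytoskeleton and contractile genes 3 fell, Tagln at −1.06, Myl9 at −0.67 and Ankrd1 at −0.48 (adjusted p = 0.00778, lost at adjusted p = 0.539 with an estimated correlation), or 6 adjusted over the list alone. Here the median was 0.03 on Exp 1 with Exp 2 and −0.40 on Exp 3 with Exp 4.

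The other 13 lists were not shifted in the turned fit, with adjusted p from 0.0832 to 0.959 by camera. Of 35 p38 and MAPK pathway genes 4 rose and 0 fell (4 and 1 adjusted over the list alone), with the p38 substrate kinase Mapkapk2 at 0.76 and the phosphatases Dusp1 and Dusp5 at 0.71 and 0.69. In the Wnt, BMP and bone remodelling list 2 of the 36 members tested rose and 5 fell (2 and 8 adjusted over the list alone). Among those tested the largest changes were Id1 at −1.66, the decoy receptor Tnfrsf11b at 1.20 and Dkk3 at −0.84. Immediate early genes and decay factors had 1 rise, Ier3 at 2.16, and 3 falls among 26, including Nr4a3 at −1.31, whose other probe had the opposite sign, and Fos at −1.30 (2 and 3 adjusted over the list alone). Glycolysis and hypoxia genes had 2 rises and 3 falls among 28, with Bnip3 at −0.85, Hif1a at −0.69 and Adm at 0.65, saturated on some arrays (3 and 3 adjusted over the list alone). Adhesion molecules had 2 rises, Cd44 at 1.01 and Icam1 at 0.63, and 1 fall, Cdh11 at −0.36, among 19 (3 and 3 adjusted over the list alone). The oxidative stress list had 2 falls among 27, Gpx3 at −1.66 and Hmox1 at −0.85 (1 rise and 2 falls adjusted over the list alone). Interferon response genes had 2 rises among 31, Gbp2 at 0.73 and Irf5 at 0.49 (2 and 6 adjusted over the list alone). Synovial fibroblast markers had 1 rise and 3 falls among 18, with Dpt at 0.62 and Vim at −1.16 on the 3 arrays with a value (2 and 4 adjusted over the list alone). In the marker lists of other cell types, 0 of 21 macrophage, 0 of 14 endothelial, 0 of 15 lymphocyte and 0 of 9 pericyte genes passed over all genes, and 1 of 15 chondrocyte markers rose and 1 fell, Comp at 0.46 and Cilp at −0.36. Adjusted over the list alone, 1 macrophage marker was higher, 1 pericyte marker lower, and 1 chondrocyte marker each way. Median, mean and test differed in sign for matrix proteases and for endothelial, pericyte and synovial fibroblast markers.

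In the SB80 comparison, some matrix and inflammatory genes lay lower in the +SB80 samples, and some genes higher, with 51% of all genes lower. All +SB80 samples were assigned to Cy5 and all −SB80 samples to Cy3. A dye bias of single genes therefore cannot be told apart from SB80 in any of these ratios. Penk, the precursor of enkephalins, had a log2 fold of −1.44 ± 0.10 (SE, n = 3), the collagen gene Col8a1 −1.33 ± 0.09, Ptgs2 −1.13 ± 0.10, and lubricin (Prg4), the boundary lubricant of joints, −0.91 ± 0.10, with the same sign on 3 of 3 arrays. Higher in the +SB80 samples were Vcam1 at 0.94 ± 0.11 and the surface receptor genes Igsf6 at 1.03 ± 0.12 and Cd302 at 0.91 ± 0.10. None of these passed in the planned fit on all 7 arrays. The errors are those of a fit on the 3 SB80 arrays alone, chosen beforehand as a check and given this weight after the data were seen, in which each of the 7 passed with a limma adjusted p from 0.00871 (Penk and Col8a1) to 0.0371 (Igsf6). That fit called 12 genes higher, and 3 after correction of position gradients, so at most 3 of the 12 kept their call. Which genes kept it is not given here.

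In the planned fit 0 of 36139 genes passed, with a smallest limma adjusted p of 0.184 and 5745 genes at an unadjusted p under 0.05 against 1807 expected by chance. The one-sample t called 0, the channels as separate samples 0, the processed signals called 0, as did the log ratio and the value table, the fit without Exp 3 called 1, and the 3 arrays alone 60, of which 12 were higher and 48 lower. After correction of position gradients the 3 arrays alone called 52, 3 higher and 49 lower, and 34 of the 60 were among them. Array weights called 12545, with weights of 2.93 and 2.54 for Exp 7 and Exp 8, which share a position gradient, and after correction of such gradients 1905. In the planned fit the TNF arrays, opposed as labelled, enter the shared estimate of spread, so that Ptgs2 had an SE of 1.18. The smallest p-values there, each with adjusted p = 0.184, belonged to Prg4 (−0.91), Col8a1 (−1.33), the growth factor receptor Fgfr1 (−0.82), the phosphatase Dusp8 (−0.77), Mrtfa (−0.73), Mast2 (−0.59), Bap1 (−0.48) and Fgf7 (−1.14). On the higher side stood Hnrnph1 (0.80), Crym (0.64), Ostm1 (0.55), Crls1 (0.52), Fam50a (0.53), Rarres2 (0.85), Mrpl44 (0.57) and Mapk14, which encodes p38 alpha itself (0.65). Another probe of Fgfr1, Hnrnph1, Ostm1, Crls1, Fam50a and Mapk14 had the opposite sign.

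In the fit of the SB80 arrays alone, the named genes that fell further included Prss23 (−1.16 ± 0.14), Mmp13 (−1.16 ± 0.11), Fgf7 (−1.14 ± 0.13), Cxcl2 (−1.10 ± 0.10) and the elastase Mmp12 (−0.86 ± 0.10). Wfdc18 rose by 0.85 ± 0.10 and Hnrnph1 by 0.80 ± 0.10. Cxcl3 also passed (−1.14 ± 0.10, limma adjusted p = 0.0213), but its +SB80 channel was saturated on 2 arrays and its other probe had the opposite sign. Probes saturated in both channels on all 3 arrays, 11 in number, had median ratios of −1.29, −1.11 and −0.23 on Exp 6, Exp 7 and Exp 8, the ratios that normalization gives a spot at the scanner's ceiling, and Cxcl3 had exactly −1.29 and −1.11 on the former 2. With saturated spots left out, Cxcl3 did not pass (−1.03 on 1 array, adjusted p = 0.108), while Cxcl2 and Mmp13 did, at −1.14 and −1.20 on 2 arrays. Of the 60 genes, 4 were saturated on at least 1 array, and 58 of the 60 were among the 68 called without saturated spots. Besides Cxcl3, Cldn9 was lost (−0.83, then −0.79 on 1 array with an adjusted p of 0.155), named after its values were seen. Of the 19 core genes 4 passed (Cxcl2, Mmp13, Ptgs2 and Vcam1) and 12 adjusted over the list alone, but Ccl2 and Mmp3, 2 of the 12, were saturated in both channels throughout and have no fold, and Ccl20, another, turned from −0.70 to 0.16 (adjusted p 0.688) on the 1 array left without saturated spots. Core genes that did not pass over all genes included Il6 (−0.60 ± 0.12, adjusted p = 0.0983), Csf2 (−0.74 ± 0.12, adjusted p = 0.0696), Dusp1 (−0.45 ± 0.11), Mmp9 (−0.43 ± 0.11) and Ptges (−0.38 ± 0.11). Ccl5 had 0.31, Cxcl10 0.14, Nos2 −0.13, Icam1 −0.05, Nfkbia −0.20 and Sod2 0.22, and Cxcl1, saturated on all 3 arrays in the +SB80 samples, was uncalled.

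**Figure D3:**
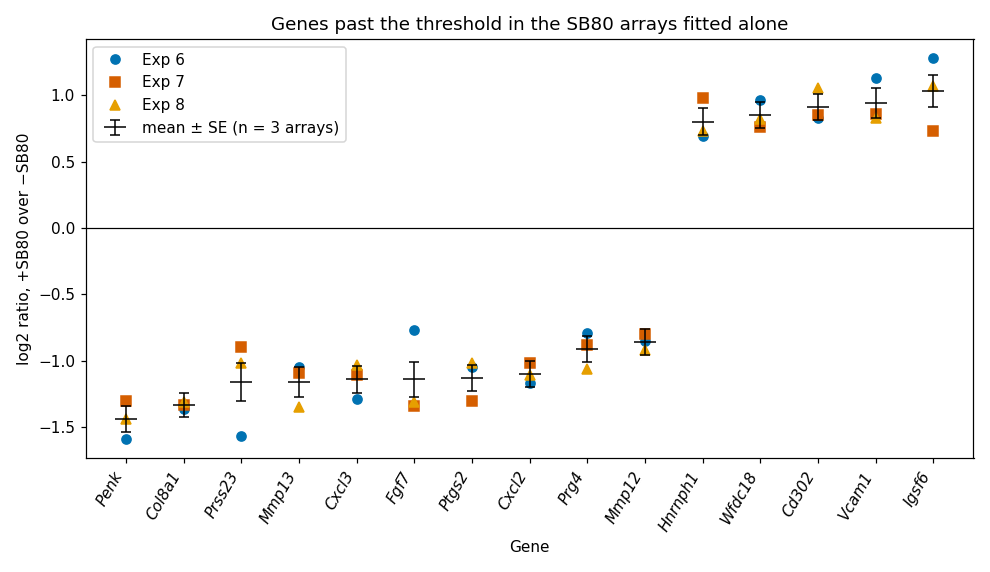
Log2 ratio of +SB80 over −SB80 (vertical axis) for genes given in the text that were past the threshold in the SB80 arrays fitted alone (horizontal axis). Points are arrays, black bars the mean ± SE of 3 arrays, from Penk at −1.44 to Igsf6 at 1.03, and 2 of the 3 Cxcl3 points are saturated spots.

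Of the 24 lists, 2 were shifted in the planned SB80 fit, both downwards. Fibrillar matrix and matrix assembly had a median of −0.23 with 31 of 42 genes below 0 (camera adjusted p = 0.0211, lost at adjusted p = 0.955 with an estimated correlation), and glycolysis and hypoxia a median of −0.28 with 21 of 28 below 0 (adjusted p = 0.0211, lost at adjusted p = 0.648 with an estimated correlation). With median centring in place of loess the glycolysis list changed direction (adjusted p = 0.994) and the matrix list was not past the threshold, and with array weights neither list was. No member of either passed over all genes. Adjusted over the list alone, 2 matrix genes were lower, Col8a1 and the lysyl hydroxylase Plod1 (−0.58). In the glycolysis list 5 were lower, the glucose transporter Slc2a1 (−0.98), the lactate transporter Slc16a3 (−0.82), Aldoa (−0.73), Pfkl (−0.54) and Car9 (−0.32), and 1 was higher, the hexokinase Hk1 (0.36). In other lists the genes adjusted over the list alone were Itga1 (−0.61), Itgav (−0.47), Sox9 (−0.67), Irf7 (0.68), Dusp8, Mapk14, the hyaluronan synthase Has2 (−1.01) and Prg4, named, like those of the 2 shifted lists, after their values were seen. The remaining 22 lists had adjusted p from 0.167 to 0.919, among them chemokines (median −0.17), cytokines (−0.30), matrix proteases (−0.35) and immediate early genes (−0.18). Median, mean and test differed in sign for the cell cycle, p38 and MAPK, endothelial and lymphocyte lists. With the SB80 arrays alone 6 lists were shifted, without Exp 4 there were 4, and without Exp 6 there were 0. In the fit with Exp 2 and Exp 3 turned 7 lists were shifted, all downwards and 3 of them with an estimated correlation, and 63 genes passed, 18 higher and 45 lower, of which 27 were among the 60 of the SB80 arrays alone. That fit called 1 gene with a dye term, 2 with block correction and 0 with both.

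Set side by side as labelled, the 2 comparisons shared 0 called genes of opposite sign and 0 of the same sign by limma, since neither called any. Their log2 fold changes correlated across 36139 genes at −0.28 (Pearson) and −0.28 (Spearman), where genes are not independent replicates. The +TNFa samples were all in Cy3 and the +SB80 samples all in Cy5, so a dye bias of single genes also gives a negative value as labelled. With Exp 2 and Exp 3 turned, which balances the dyes of the TNF comparison, the correlation over all genes was −0.06 (Pearson) and −0.01 (Spearman), and over the 1548 called genes −0.27 (Pearson). Of the 719 genes that rose in the turned fit, 463 (64.4%) were lower in the +SB80 samples, against 51% of all genes, and of the 829 that fell, 487 (58.7%) were higher. Turning Exp 1 and Exp 4 in place of these reverses each of these directions.

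Among genes called in both comparisons, Ptgs2 (2.85 against −1.13), Penk (1.57 against −1.44), Cxcl2 (5.73 against −1.10), Mmp13 (2.34 against −1.16) and Mmp12 (1.94 against −0.86) had opposite signs, the TNF arrays being turned and the SB80 arrays fitted alone. In all 26 genes did so, 20 of them higher in the turned TNF comparison where 0.955 would be shared by independent lists, and 4 had the same sign. Fisher's exact test on the overlap of the 2 sets of calls, signs ignored, gave p = 2.33e-25, with genes not independent. The split into opposite and same signs was not itself tested. With SB80 taken from the joint turned fit the counts of opposite and same sign were 22 and 6, and with saturated spots left out 26 and 7. In the joint turned fit with a dye term 1 gene had opposite signs, with block correction 2, and with both corrections 0, since SB80 then called 1, 2 and 0 genes. Wfdc18 also had opposite signs, but was lower in the turned TNF comparison (−1.65) and higher in the +SB80 samples (0.85). Igsf6 and Prss23 had the same sign in both (0.67 and 1.03, −1.11 and −1.16). Nfkbia, Birc3 and Il1b, high in the turned TNF comparison, did not pass in the SB80 arrays, with Nfkbia at −0.20.

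**Figure D4:**
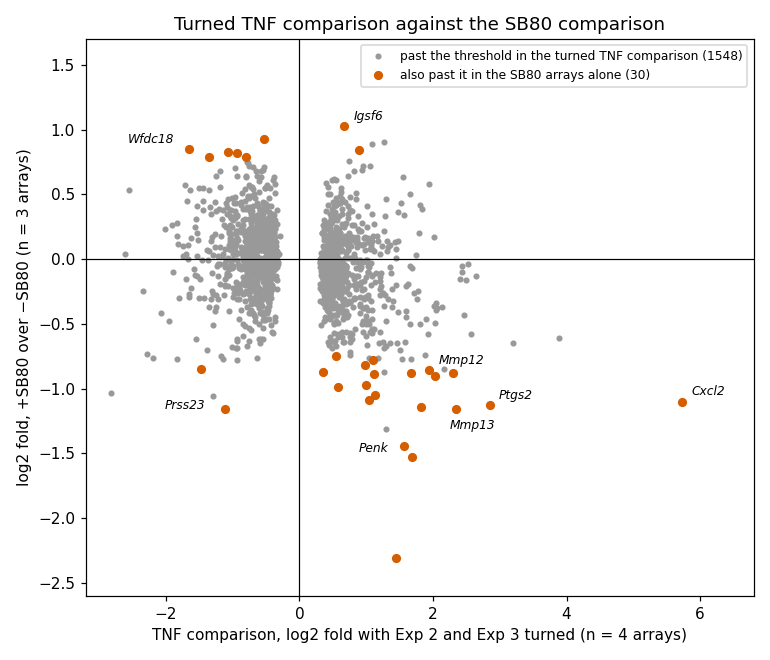
Log2 fold of +SB80 over −SB80 (vertical axis, n = 3 arrays) against the log2 fold of the TNF comparison with Exp 2 and Exp 3 turned (horizontal axis, n = 4 arrays) for the 1548 genes called in the latter. Orange points are the 30 genes also called in the SB80 arrays alone, 26 of them of opposite sign, with Cxcl2 farthest to the right at 5.73 and −1.10.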

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

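The tests on opposed arrays, on dye swaps, on the opposition of TNF and SB80, and on the arrangements of the turned fit were chosen after the result was seen; those on other splits of the samples as labelled were planned.

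Among named genes, 3 had an array far from the other 3 of its group. The log2 ratio of Crh as labelled was −0.26 on Exp 2 against −0.21 to −0.20 on the others, a gap that is small in size. Ankrd1 in the turned comparison was −0.84 on Exp 2 against −0.40 to −0.32. Cxcl3 in the turned comparison was 2.63 on Exp 3 against 1.48 to 1.66, with saturated spots on all 4 arrays. Such gaps were found in 1 of 34 groups of values as labelled and 2 of 72 turned, in 0 of 48 list medians and in 0 of 6 array measures, where chance gives about 1 in 20. Many named genes were chosen for 1 sign on every array or for a small p, which favours close values. That rate therefore does not hold for them, and the counts cannot show that outlying arrays are few.

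The log ratios of the 4 TNF arrays opposed each other as labelled. A bias that goes with the dye would give every pair a positive correlation, since all 4 have the +TNFa label on Cy3. Exp 1 and Exp 2 correlated at −0.55. Background correction or normalization was varied, and the highest correlation of these arrays was −0.43 across 33769 probes well above background, and −0.06 across all probes, dim ones included, so these steps do not account for it in bright probes. A candidate explanation is that the channels of 2 arrays were assigned to the opposite sample: for 8 of 8 TNF channels the nearest channel on another TNF array lay inside the grouping that turns Exp 2 and Exp 3, and for 7 it carried the opposite label, against 1 of 6 SB80 channels. The grouping came from the correlations of these same arrays, so the count inside it largely restates them and is not separate support. Which 2 arrays would be the turned ones was not decided. A real difference in response between cultures was not tested. If untreated cells were alike, it would leave the −TNFa channels nearest each other. Those of Exp 1 and Exp 2 differed by a root mean square log2 of 0.42. The −TNFa channel of Exp 1 and the +TNFa channel of Exp 2 differed by 0.29. For that pair these values argue against a difference in response alone. The −TNFa channels of Exp 3 and Exp 4 differed by 0.55, against 0.40 and 0.49 for their channels of opposite label. These values argue against it for Exp 3 and Exp 4 too, but less firmly, since Exp 3 has a position gradient.

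The channels of Exp 1 and Exp 2 matched across labels, which may mean a dye swap of the same 2 extracts. Their matched channels differed by a root mean square log2 of 0.27 and 0.29, less than the smallest difference of other channels on different TNF arrays, 0.36. For Exp 3 and Exp 4 the matched channels differed by 0.40 and 0.49, more than the smallest other difference of 0.27, which is itself the match of Exp 1 with Exp 2, and more than the 0.36 left without that pair. Exp 3 has a position gradient, so a dye swap and separate extracts cannot be told apart there. If each pair is a swap, the TNF comparison has 2 replicates, and the pairs averaged called 385 genes.

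Genes called in the turned TNF comparison tended to move the other way with SB80, with a correlation across the 1548 genes of −0.27 (−0.30 to −0.20 leaving out each array). Dye bias as the whole cause was predicted to bring it near 0 once a dye term was fitted, and it was −0.35 (−0.44 to −0.15). Turning already balances the dyes of the TNF comparison, so this prediction could hardly come true and decides nothing about dye bias. Position gradients as the cause would bring the correlation near 0 after block correction, but it was −0.34 (−0.35 to −0.31). An opposition of p38 inhibition to the TNF response is then a hypothesis suggested by these values, and it holds only in the direction of Exp 1 and Exp 4. It also assumes that the samples labelled −SB80 had TNF, which is not stated outright.

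With channels taken as separate samples, the real TNF split called 0 genes, a count that any split reaches (35 of 35), so this says nothing about chance. The highest other count, 1782, came from the split of Exp 1 and Exp 2 against Exp 3 and Exp 4, which follows the shared extraction day of the former and points to a structure of the samples. With the arrays of that day averaged the count as labelled was 0. For SB80 the real count was also 0, reached by 10 of 10 splits by construction, and the highest other, 1805, set both channels of Exp 6 with the −SB80 channel of Exp 7 against the rest, again a structure of the samples. Those 10 splits are too few for a share under 0.05.

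The sign arrangements by array are too few for a share under 0.05 in every case. Where the real count was 0, every arrangement reaches it and nothing was tested: 8 of 8 for TNF genes as labelled (highest other 1548), 4 of 4 for SB80 genes (highest other 0) and 8 of 8 for TNF lists (highest other 11). For SB80 lists 1 of 4 reached the real 2 (highest other 1). For the turned fit 1 of 8 reached 1548 genes (highest other 2) and 1 of 8 reached 11 lists (highest other 6). The arrangement with 1548 genes points to a structure of the samples in the as-labelled comparison.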

How the results depend on the processing

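The turned directions, dye terms, block corrections, the omission of saturated spots and the averaging of pairs were tests chosen after the result was seen; the others were planned. The cause of a change was not tested unless stated.

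The TNF comparison as labelled called 0 genes under 27 alternatives. It called 47 with processed signals, 45 with the scanner log ratio and 43 with the value table. Turning Exp 2 and Exp 3, or Exp 1 and Exp 4, gave 1548, a dye term with the former 1473, block correction 2219, and both 2173. Leaving out any array gave 0. Shifted lists went from 0 to 1 with array weights, to 11 under either turning and with the dye term, and to 10 with block correction, with or without the dye term. Leaving out an array gave 0 to 4.

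For SB80, 0 genes became 60 with its arrays alone, 52 with these block-corrected and 68 with saturated spots left out. Fewer arrays, without the opposed TNF arrays, set the spread there. Array weights gave 12545, and 1905 after block correction. Turning Exp 2 and Exp 3, or Exp 1 and Exp 4, gave 63, the dye term 1 and block correction 2. Leaving out an array gave 0 to 1, the 1 being without Exp 3. The 2 shifted lists became 0 with median centring, with array weights and with an estimated correlation, and 1 with saturated spots left out. They became 6 with the arrays alone, 8 with these block-corrected and 5 with saturated spots left out. Either turning gave 7, and the dye term, block correction and both together 9 each. Leaving out an array gave 0 to 4 (0 without Exp 6, 4 without Exp 4). Glycolysis and hypoxia changed direction with median centring, at an adjusted p of 0.994.

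Genes called in both comparisons with opposite sign numbered 0 as labelled and under 31 alternatives, 22 with Exp 2 and Exp 3 turned, 6 with Exp 1 and Exp 4 turned, 1 with the dye term and 2 with block correction. The correlation of −0.28 was −0.32 with offset 10, −0.37 with processed signals, −0.41 with median centring, −0.39 with the log ratio, −0.37 with the value table and −0.20 with array weights. It ran from −0.30 to −0.19 leaving out an array. Block correction gave −0.36, on all arrays −0.37, for the arrays alone −0.36 and with array weights −0.40. Turning Exp 2 and Exp 3 gave −0.06, with a dye term −0.17, with block correction −0.12 and with both −0.19. Turning Exp 1 and Exp 4 gave 0.06, reversed by construction.

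The 1548 genes of the turned fit became 939 with processed signals, 709 with median centring, 953 with the log ratio, 934 with the value table and 933 with the TNF arrays alone. Averaging the arrays of 1 extraction day gave 811, and averaging Exp 1 with Exp 2 and Exp 3 with Exp 4 gave 385, with fewer replicates by construction. A one-sample t gave 0, an adjusted p under 0.01 gave 665 and a log2 fold of at least 1 gave 289. Leaving out an array gave 747 to 1540 (747 without Exp 1, 799 without Exp 2). The 11 lists became 5 with an estimated correlation and 10 to 11 leaving out an array. Of 51 named genes called there, 23 still passed with pairs averaged, and none with a value changed sign in the alternatives run on them, apart from turning Exp 1 and Exp 4, which reverses all by construction. With saturated spots left out 48 of the 51 had a value.

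Pairing matters most for the turned result: with no replicate block, that is with channels as separate samples, 181 genes were called in place of 1548, and as labelled 0 for TNF and 0 for SB80. A random effect of extraction day could not be estimated, so the arrays of a day were averaged. A dye term as labelled was not run, because all arrays of a comparison share 1 orientation.

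Among single named genes, TNF values as labelled newly passed in 9 combinations of gene and alternative (Creb3l3, Apoc4 and Dgkh with processed signals, the log ratio and the value table), moved in 67 and kept direction and side of the threshold in 896. SB80 values newly passed in 106 and moved in 16, against 1291 that kept direction and side of the threshold. Turned TNF values lost their call in 317 and gained it in 6, and kept direction and side of the threshold in 1744. Signal limits both ends. Between 85.7% and 97% of probes were well above background, and between 14 and 359 were saturated per channel, so that Ccl2 and Mmp3 give no fold for SB80.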

Other observations

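The tests below on scanner-software calls, position gradients and saturation were chosen after the result was seen.

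Several members of raised lists fell in the turned TNF comparison, named after their values were seen. Bcl3, a nuclear partner of NF-kappaB, had a log2 fold of −0.86, the chemokine Cxcl12 −1.25, the growth factor Tgfb3 −1.43, the prostaglandin F receptor Ptgfr −0.80, and the proteases Adamts9 −0.96, Ctsk −0.77 and Mmp23 −0.50. In the other direction the plasminogen activators Plat and Plau rose by 2.03 and 1.08, the protease inhibitor Timp1 by 0.75 and the acute phase gene Lbp by 0.97. As for all turned values, each sign reverses if Exp 1 and Exp 4 are turned in place of Exp 2 and Exp 3.

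Of the 47 genes that processed signals called in the TNF comparison as labelled, 41 had the opposite sign in the SB80 comparison, against 60.6% of all genes. The +TNFa samples were in Cy3 and the +SB80 samples in Cy5, and no test here parts a dye effect from the labelled treatments in those calls.

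Ratios on Exp 7 and Exp 8 changed with the row on the array, with correlations across probes of −0.623 and −0.64, and with the column at −0.294 and −0.437. On Exp 3 and Exp 6 they changed with the column, at −0.267 and 0.286. Subtracting block medians lowered the median SD over repeated spots from 0.281 to 0.094 on Exp 7, from 0.272 to 0.0867 on Exp 8, from 0.233 to 0.15 on Exp 3 and from 0.099 to 0.0827 on Exp 4. It raised that SD from 0.0579 to 0.0733 on Exp 1, from 0.0395 to 0.0745 on Exp 2 and from 0.059 to 0.133 on Exp 6, and the correction of improved arrays leaves these 3 as they were. Exp 7 and Exp 8 correlated at 0.78 before the correction and 0.56 after it. Exp 6 correlated with Exp 7 at 0.15 and with Exp 8 at 0.10 before it, and at 0.35 and 0.36 after it.

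The means of Exp 1 with Exp 2 and of Exp 3 with Exp 4, turned, correlated at 0.46 across all genes and 0.88 across the 1548 called ones, which were called on the same arrays.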
